A study of Homo sapiens with 2 samples.

How the data were processed

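macroH2A1 is a histone H2A variant that carries a large macro domain at its carboxyl end. Its distribution along the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in IMR90 cells, a human fetal lung fibroblast line. The cells had received a retrovirus encoding H-RasV12, an activated oncogene that drives normal fibroblasts into a lasting growth arrest called oncogene-induced senescence, and were kept under 1 µg/ml puromycin for 14 days. Per the labels' protocols, chromatin was fixed with 1% formaldehyde for 10 min and sonicated to pieces of about 500 bp. The labels give 1 ChIP library and 1 input library, the latter being sonicated chromatin without immunoprecipitation, and each is replicate 1 of its group. No proliferating cells were analysed here, so every comparison is between genomic regions within these 2 libraries.

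The authors deposited 1 table that sets the ChIP library against the input library, in hg19 coordinates per the submitters' processing notes, which also name CASAVA 1.7. The aligner, the segmentation program and any read filters are not given in the sources used here. The table held 38785 segments that tile the chromosomes end to end, so it is a division of the whole genome and not a list of peaks. Of these, 38761 lay on the 23 chromosomes used (1 to 22 and X), and the Y chromosome was left out. Each segment carries a deposited log2 value, which the values themselves show to be a log2 odds ratio of ChIP over input. The odds in a library are the reads in the segment over the rest of its reads. Where a segment holds a small part of each library, this is close to the log2 of ChIP reads over input reads. It is shifted by 1 constant that places equal library shares at 0. Each segment also carries a deposited −log10 p, which matched a one-sided binomial tail of whole read numbers: the upper tail where the log2 ratio was above 0 and the lower tail below it. Depleted segments with a −log10 p beyond 6.25 were listed at 0 (15769 segments), and 280 enriched segments stood at the top of the column, 307. Adjusted p-values were not filled in. The block column gives the parts of a segment left after runs without data. The p-values are not independent tests, because the borders of the segments were chosen on the same reads.

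Whole read numbers were recovered from the log2 ratio and the p of each segment, by searching for the pair of ChIP and input numbers that gives both. The search needs the share of ChIP reads in the 2 libraries, which was fitted from the deposited values: the ChIP total was 1.40 times the input total. The search also needs the input total, which was fitted from the drift of the log2 odds ratio with the read numbers. Numbers were found for 22728 of the 22732 segments whose p lay between the limits of its column. On 1952 simulated segments with a usable p, 100% were recovered and 0% received a wrong pair. That test was given the true share and input total, so it does not check how well they were fitted here. The implied totals were 57.5 M ChIP reads and 41.0 M input reads (M, mega). The median enriched segment held 1357 ChIP reads and 610 input reads, and the median width of its 95% confidence interval (Clopper-Pearson, on the log2 scale) was 0.28. These intervals cover counting error only, since PCR copies of a fragment are not independent molecules. No interval can be given for depleted segments listed at 0.

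The design had been written for a list of enriched peaks. The deposited table holds ratios for the whole genome instead, so a rule for domains was set after its layout was seen. A segment was called enriched when its log2 ratio was above 0 and its deposited p was 0.01 or less, depleted when its ratio was below 0 and its p was 0.01 or less (or its −log10 p was listed at 0), and neither otherwise. Touching enriched segments were joined into domains. Shares of the genome were taken over known sequence (bases other than N) of GRCh37. None of the chromosomes used ran beyond its GRCh37 length. Genes came from GENCODE release 44 lifted to GRCh37, with 20072 protein-coding genes of which at least 50% of the body lay in segments. Giemsa bands of hg19 came from circlize 0.4.16 in R 4.3.3. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

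Bands, transcription start sites (TSSs), gene bodies, exons, introns and intergenic DNA were compared with 1000 circular shifts, in which the domains of a chromosome move together by a random offset along its known sequence. Such a shift is a permutation of positions, and its two-sided placement p cannot go below 0.002 with this number of shifts. Clustering was compared with 1000 random placements of the same domains without overlap. Tested on simulated domains placed at random, the TSS share was 0.994 times that of the shifts over 20090 TSSs. After removal of 4 kb around 4000 of these TSSs, it was 0.763 times, where the windows removed gave an expectation of 0.764 times.

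Coverage of a gene is the percent of its body, from TSS to end, that lies in domains. For 16 gene lists and 5 families given by a symbol pattern, the mean coverage was set against 10000 random lists, each member being replaced by 1 of the 100 protein-coding genes nearest in length. The position of a list is given as its percentile among these lists. This exchange of members for matched genes is a permutation test, and its two-sided random-list p was adjusted over the 21 lists by the Benjamini-Hochberg method, and a list was called at an adjusted value under 0.05. Genes are not replicates, so the percentile describes these 2 libraries. Among 1000 simulated lists of 30 genes drawn at random, 4.9% were called at an unadjusted 0.05. With the coverage of 15 or 25 of the 30 members set to 0, 56% and 100% of 100 lists fell into the lowest 2.5% of random lists. Since 59.0% of measured genes had no coverage to begin with, fewer members than that changed on average. These rates therefore hold for smaller effects than 15 and 25 changed members. The larger effect, and 1000 in place of 100 lists drawn at random, were added after a first run, in which more of the random lists were called than the threshold allows. Random lists are scattered over the genome, so percentiles of families that sit in few clusters overstate their precision, and counting neighbours within 1 Mb as 1 locus was among the alternatives.

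The rule for named genes, the lists, the tests and a first set of other settings were fixed before the data were examined, with these exceptions. The plan ranked the top 10 genes by the value of their domain, in place of which their own mean log2 ratio was used. The count of bins with no domain and the classes of gene length were not in the plan. All members of the list of secreted senescence factors could be named; for other lists, up to 2 members with the highest and 2 with the lowest coverage (ties going to the longer gene), and no more than 2 members of a family; the 10 genes with the highest mean log2 ratio among those with the TSS in a domain and at least 90% coverage; and the 10 widest domains with up to 3 of their longest genes. Single values of some genes that this rule takes in are not reported here, while the lists hold all measured members. That first set held a stricter p, inner blocks in place of whole segments, domains of 5 kb or more, domains under 10 kb apart joined, autosomes only, other denominators, promoter windows of 1 kb on each side, matching on gene density, neighbours counted as 1 locus, the largest locus of secreted factors left out, the share of members covered over at least 50%, all annotated genes, bins of 250 kb, and the other columns of the table in place of the log2 ratio. Alternatives chosen after seeing the data were any log2 ratio above 0, a log2 ratio of 0.5 or more, an adjusted p of 0.01, matching on GC content, the median log2 ratio of a list in place of its coverage, and all annotated genes or a domain within 1 kb of the TSS together with each other set of domains.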

Results

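The data collected were 1 macroH2A1 ChIP library and 1 input library from IMR90 lung fibroblasts in H-RasV12-induced senescence. The series describes where macroH2A1 lies in these senescent cells. The deposited log2 ratios imply 57.5 M ChIP reads and 41.0 M input reads in total. There were no replicates, so no value below has a replicate error, and tests of placement or gene lists describe these libraries. Log2 ratios are ChIP over input as scaled by the authors, and positions are 1-based in hg19.

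macroH2A1 formed broad domains. Enriched segments covered 47.3% of known sequence (1342 Mb), depleted segments 42.9%, and segments that passed neither test 9.63%. The median log2 ratio was 0.67 in 12696 enriched segments (quartiles 0.43 and 0.94), a 1.59-fold ratio, and -1.54 in 19355 depleted segments (quartiles -2.51 and -0.80), a ratio of 0.343. Depletion was thus further from equality on the log2 scale than enrichment. Since 0 is set at equal library shares, enrichment in one part of the genome requires depletion in another. The scaling alone can give such an asymmetry, so it is not evidence of a property of macroH2A1. Joined, the enriched segments gave 8331 domains with a median width of 49.8 kb, and the 2757 domains of 100 kb or more held 87.2% of the domain length. The median log2 ratio was 0.96 in 1761 enriched segments under 10 kb and 0.38 in 999 over 300 kb. A narrow segment, with few reads, needs a higher ratio to reach the p required of enriched segments, and the median −log10 p of these classes was 6.46 and 71.7. Spearman's rho between width and log2 ratio was -0.37 across enriched segments, which are not independent of each other. It was -0.12 across all segments with a log2 ratio above 0, where no p was required (chosen after seeing the data). A log2 ratio of 0.5 or more, chosen after seeing the data, left 22.1% of known sequence in domains.

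The X chromosome had the highest share of its sequence in domains. On X, 72.9% of known sequence lay in domains against 45.9% on the autosomes together, whose shares ran from 28.8% on chromosome 4 and 33.5% on chromosome 13 to 60.3% on chromosome 16 and 61.0% on chromosome 20. macroH2A1 is known in the field for its concentration on the inactive X chromosome of female mammals. The median log2 ratio of the enriched segments on X, 0.53, was the lowest of the 23 chromosomes, and chromosome 22 had the highest, 0.86. That median counts each segment once, and wide enriched segments had lower ratios. Averaged by length over all segments, X had the highest log2 ratio, 0.22, and that of every autosome was negative. Depleted segments took up 16.1% of the segmented length of X, the lowest share. Among protein-coding genes, 62.6% of 850 X-linked TSSs lay in a domain against 30.4% on autosomes. Counting only segments with a log2 ratio of 0.5 or more, X ranked 15 of 23 with 20.5%, below the autosomes at 22.2%. Chromosomes are not replicates, and no test was made between them.

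**Figure D1:**
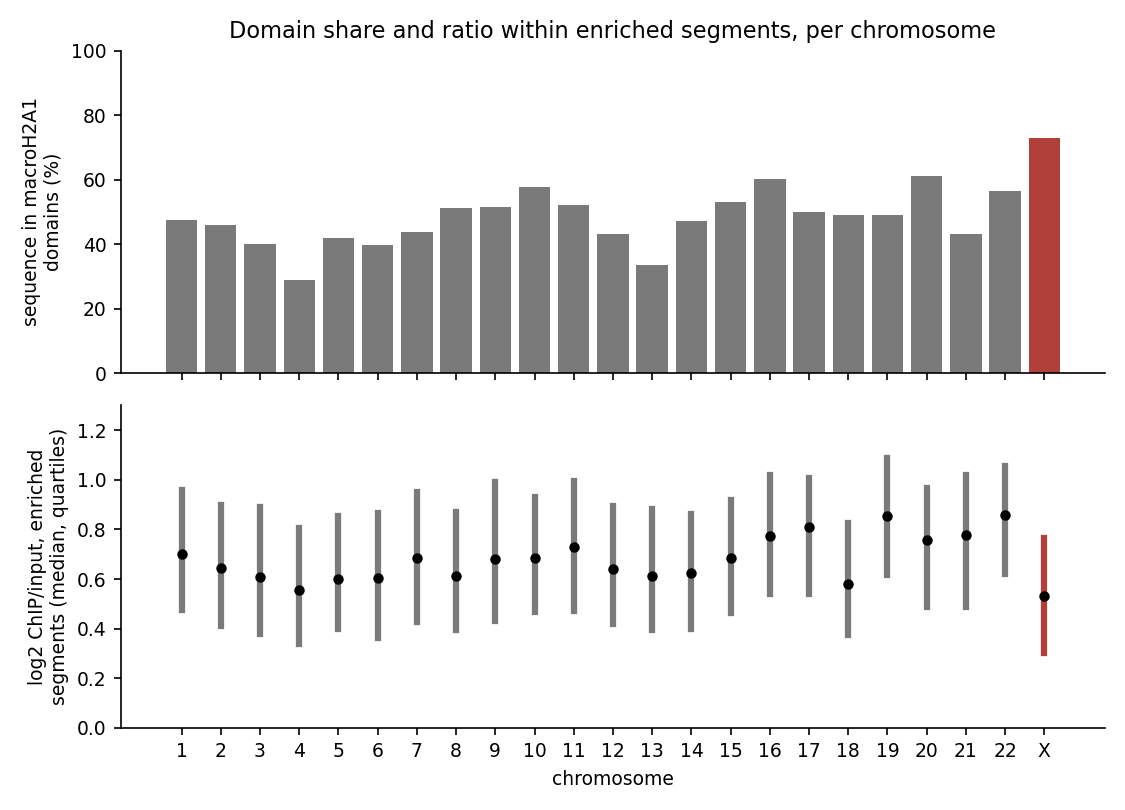
Top, percent of known sequence in macroH2A1 domains for chromosomes 1 to 22 and X (bars), with X at 72.9% and chromosome 4 at 28.8%. Bottom, median (points) and quartiles (lines) of the log2 ChIP to input ratio of the enriched segments of each chromosome, where X has the lowest median, 0.53.

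Starts and bodies of protein-coding genes were poor in macroH2A1, and DNA between genes was rich in it. Of protein-coding TSSs, 31.8% lay in a domain, 0.653 times the 48.6% that circular shifts gave on average (permutation of positions, placement p = 0.002, the smallest that 1000 shifts allow). At a log2 ratio of 0.5 or more, TSSs of all annotated genes turned to 1.09 times the shifts (26.7% against 24.4%, with the same smallest permutation p), and protein-coding TSSs with a domain within 1 kb did not pass (0.949 times, permutation p = 0.118). Domains covered 29.7% of gene bodies (0.626 times the shifts), 30.2% of introns (0.638 times), 23.7% of exons (0.492 times) and 62.3% of intergenic DNA (1.32 times), each with the same smallest p. The median log2 ratio was 0.14 at 10 kb upstream of TSSs, -1.30 at the TSS and -0.96 at 10 kb downstream. The share of positions in domains fell between 5 kb upstream (47.3%) and the TSS, and rose slowly along the transcribed side, reaching 39.3% at 50 kb. At 10 kb, the upstream share exceeded the downstream share by 15.1 percentage points, while the shifts gave differences from -0.74 to 0.76. Short genes were covered most, from a mean of 49.4% in the shortest of 10 length classes (2008 genes) to 26.0% in the ninth. Of 20072 measured genes, 11844 had no base in a domain and 5276 were covered over at least 90% of their body.

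**Figure D2:**
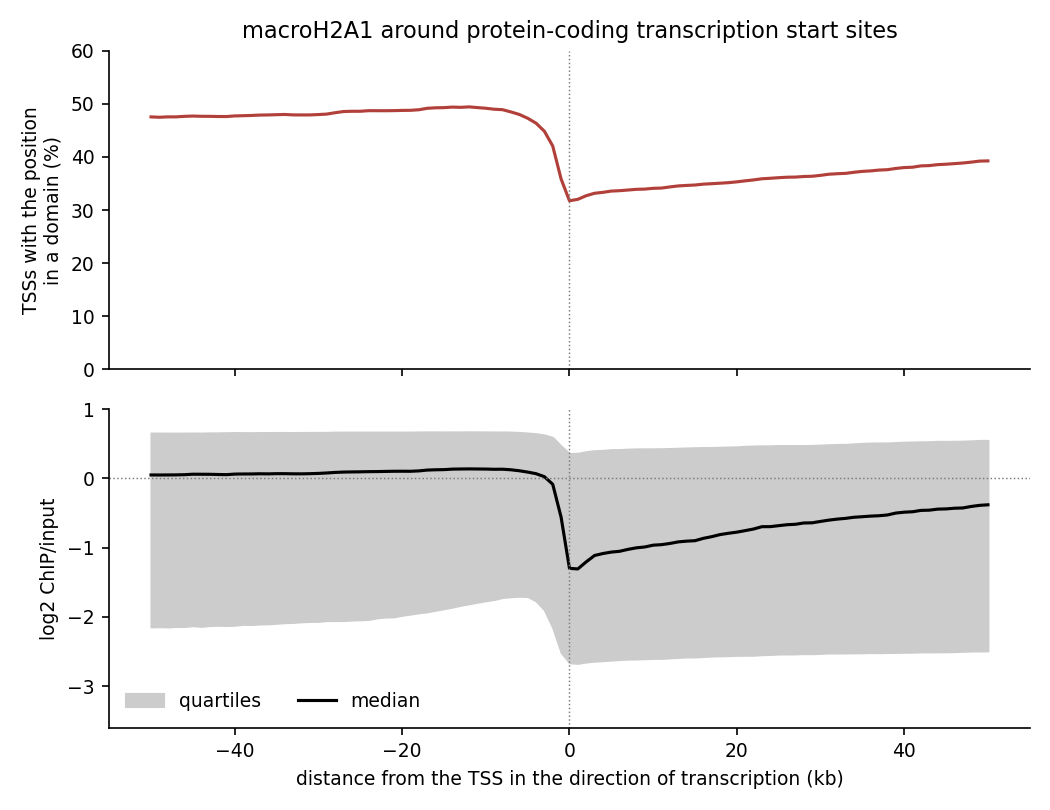
Top, percent of protein-coding TSSs whose position at the given distance (kb, in the direction of transcription) lies in a macroH2A1 domain. Bottom, median (line) and quartiles (grey) of the log2 ChIP to input ratio at the same positions. The share is 49.2% at 10 kb upstream and 34.1% at 10 kb downstream, with the steepest fall just upstream of the TSS.

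The senescence-associated secretory phenotype (SASP) is the set of cytokines, chemokines, growth factors and proteases that senescent cells release, and most of its genes lay in chromatin low in macroH2A1. Of 41 SASP genes, 35 had no base in a domain, as did 59.0% of all measured protein-coding genes. Of the 41, 31 had their TSS in a depleted segment, 4 in a segment that passed neither test and 6 in an enriched segment. Mean coverage was 14.6% against 35.1% for length-matched lists (percentile 0.08; permutation against matched genes, random-list p = 0.0018, adjusted over 21 lists 0.00252). In 2 alternatives chosen after seeing the data the list was not called. At a log2 ratio of 0.5 or more its coverage was 12.2% against 24.7% (percentile 1.98; permutation, adjusted random-list p = 0.0571), and its median log2 ratio, -1.77, stood at percentile 12.3 (permutation, adjusted random-list p = 0.266). The lowest mean ratios were those of PLAUR, the urokinase receptor, at -3.11, and MMP14, a membrane-bound collagenase activator, at -3.10, followed by PLAU, the urokinase itself (-2.98), TNFRSF11B (-2.96) and IL1B (-2.83). IL6 (chromosome 7, 22765503 to 22771621) lay in a depleted segment of 9.58 kb at -1.94, and IL1A, whose product stands at the head of the inflammatory branch of the SASP, in one of 14.2 kb at -1.87. VEGFA (-2.68), INHBA (-2.53), MMP1 (-2.43), CSF3 (-2.27) and HGF (-2.21) were also below the median of all measured protein-coding genes, -1.17. Of these, all but VEGFA stood above the lower quartile of all genes, -2.55, so such values are common among genes. Of the 35 genes outside domains, 15 lay within 10 kb of a domain, and the median distance was 13.4 kb.

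The 6 covered SASP genes came from 3 loci. CCL2, CCL7, CCL8 and CCL13, genes for monocyte-attracting chemokines, shared 1 enriched segment on chromosome 17 (32530511 to 33249484) with a log2 ratio of 0.98. CCL20 on chromosome 2 lay in a segment of 181 kb at 0.59 (95% interval 0.52 to 0.66, from 4709 ChIP and 2230 input reads). TIMP1, a metalloproteinase inhibitor on the X chromosome, lay in a segment of 36.3 kb at 0.36 (0.23 to 0.50), and had no coverage under a stricter p or at a log2 ratio of 0.5 or more. The CXCL chemokine locus on chromosome 4 differed from the CCL locus. CXCL8, the neutrophil attractant also called interleukin 8, stood at -1.57, CXCL2 at -1.91 and CXCL3 at -1.82. Between CXCL8 and CXCL3, CXCL1 was at -0.39 in a segment of 79.0 kb, CXCL5 at -0.02 (-0.19 to 0.15) and CXCL6 at a mean of 0.13. EREG and AREG, which encode ligands of the EGF receptor at the same locus, were at -2.20 and -0.52. Among the matrix metalloproteinases of chromosome 11, MMP1 was at -2.43, MMP10 at -1.28, MMP3 at -0.83 and MMP12 at 0.07 (-0.13 to 0.26).

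**Figure D3:**
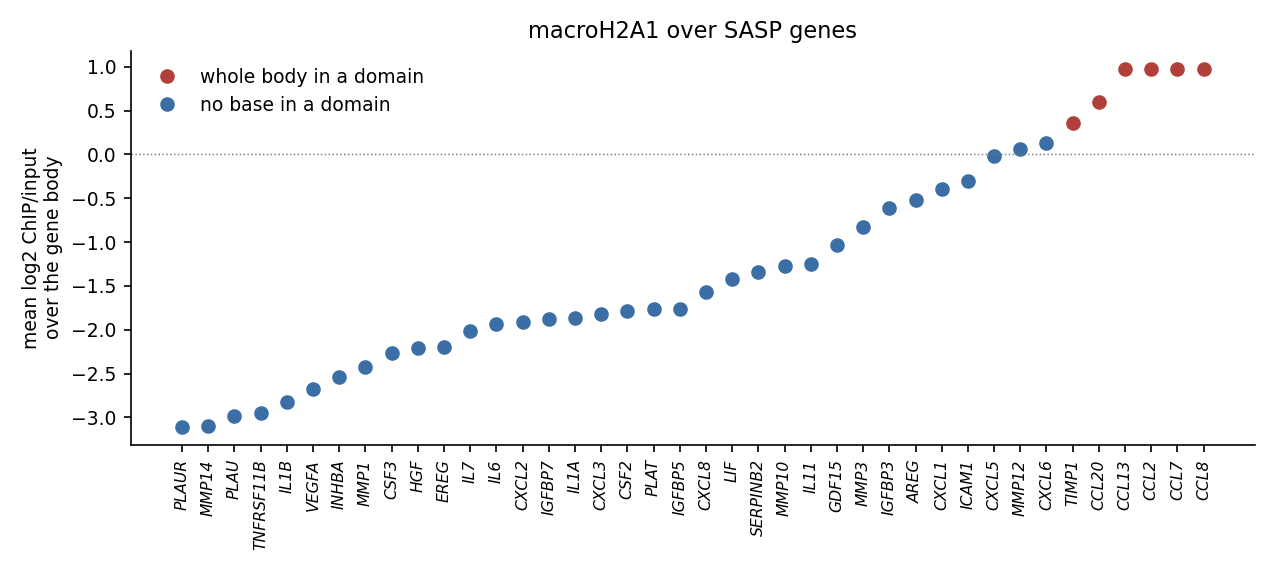
Mean log2 ChIP to input ratio over the gene body for the SASP genes reported singly, in rising order. The 6 genes wholly inside a domain (red) run from 0.36 for TIMP1 to 0.98 for the 4 CCL genes of chromosome 17, and genes without a base in a domain (blue) reach down to -3.11 for PLAUR.

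**Figure D4:**
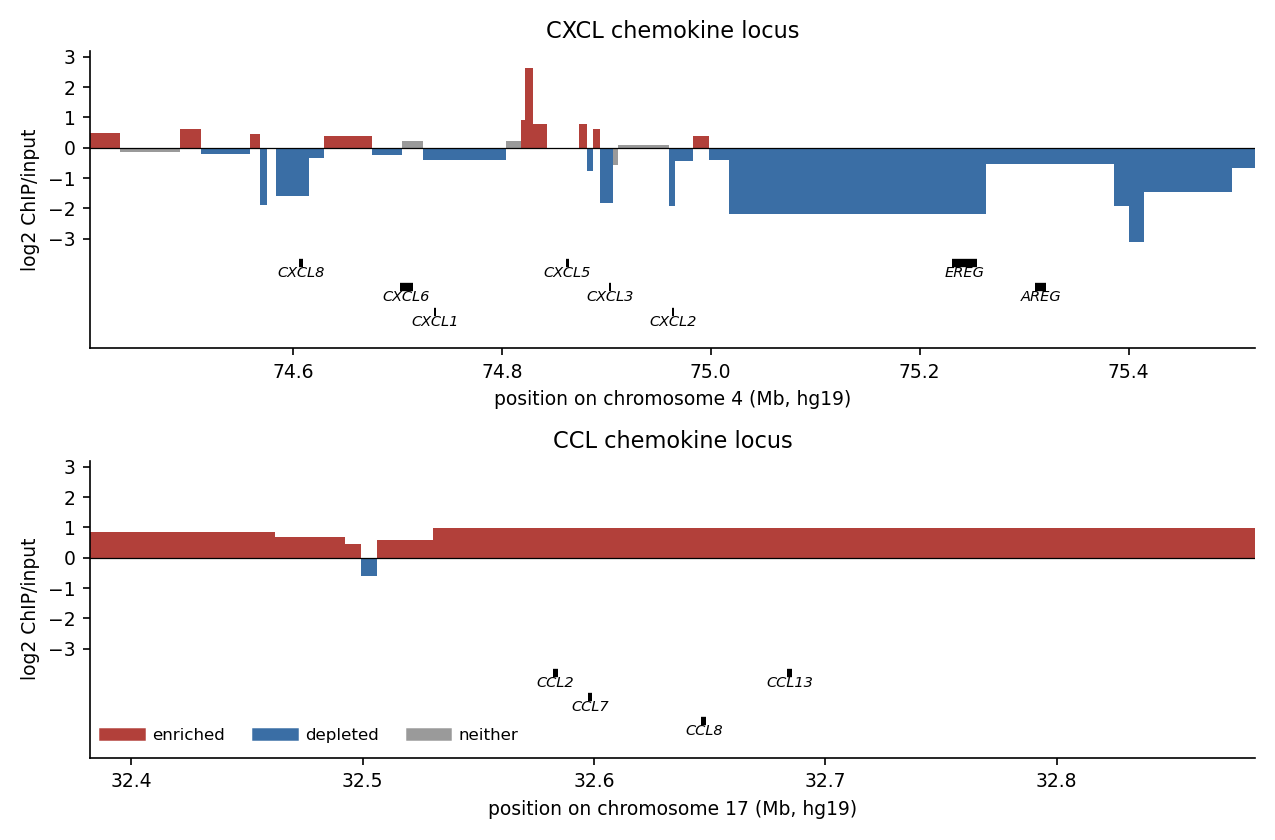
Log2 ChIP to input ratio of each segment (height; red enriched, blue depleted, grey neither) along 2 chemokine loci, against hg19 position in Mb, with genes as black bars. CXCL8, CXCL2 and CXCL3 lie in depleted segments, and CCL2, CCL7, CCL8 and CCL13 share 1 enriched segment at 0.98.

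Lists of housekeeping, fibroblast, DNA damage, senescence arrest, unfolded protein response and chromatin genes were poor in macroH2A1. Housekeeping genes had a mean coverage of 4.07% and a median log2 ratio of -2.82, with 0 of 30 members covered over at least 50% of their body. Fibroblast matrix and identity genes stood at 3.85%, and 25 of 26 had no base in a domain, FBN1 (fibrillin, -2.78) and COL5A1 (a collagen chain, -2.05) among them. The 1 exception was THY1, a surface protein used to mark fibroblasts, which was wholly covered at 0.67 (0.60 to 0.75). DNA damage response genes stood at 3.08%, with ATM, the kinase that senses double-strand breaks, at -3.22 and PRKDC at -2.98, while BLM was covered over 53.7% of its body. Genes of senescence arrest and growth control stood at 4.89%. HMGA2, a chromatin protein of senescence foci, was at -3.49, HMGB1 at -0.72, and CDKN1B, a cyclin-dependent kinase inhibitor, was covered over 75.2% with a mean log2 of 0.03. Unfolded protein response genes stood at 6.34% (DNAJC3 -2.80, ERN1 -2.72; ATF3 covered over 72.1%). Histone variant and chromatin genes stood at 6.28%; HIRA, a chaperone for histone H3.3, was at -2.99, ATRX at -0.58, and MACROH2A2, the gene of the sister variant, was covered over 63.8%. Under a stricter p and at a log2 ratio of 0.5 or more alike, MACROH2A2 had no coverage, BLM 0.375% and ATF3 40.8%. Each of these 6 lists fell below length-matched lists, which averaged between 27.6% and 33.4%, with adjusted random-list p between 0.000467 and 0.00499. By the median log2 ratio, the DNA damage and the fibroblast list did not pass (permutation, adjusted random-list p = 0.0808 and 0.0552).

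Genes of other lineages were rich in macroH2A1. Mean coverage was 71.3% for liver and muscle genes (21 of 30 covered over at least 50%), 70.1% for epithelial genes (17 of 25), 66.8% for blood and endothelial genes (20 of 29) and 59.4% for neuronal genes (18 of 30), against 33.1% to 34.4% for their random lists and with adjusted random-list p between 0.000467 and 0.000764. CDH1, the epithelial cadherin, was wholly covered at 1.04 (0.98 to 1.10), as were ERG, an endothelial transcription factor, at 0.89, VWF at 0.45, the cardiac calcium channel gene RYR2 at 0.27 and RBFOX1, a neuronal splicing factor, at 0.51. At a log2 ratio of 0.5 or more, RYR2 had no coverage, RBFOX1 24.2% and VWF 19.5%, and VWF had the same share under a stricter p. Members without coverage included ROBO4, a vascular receptor, at a mean of -0.93 with its TSS in a depleted segment at -3.41, PTPRC, the leukocyte antigen CD45, at -0.65, TTN, the muscle protein titin, at -0.53, and LRP1B at -0.29. ALB (-0.03), DSP (0.04) and KRT19 (0.05) also had none, but with any log2 ratio above 0 DSP was covered over 98.7% and KRT19 wholly. Developmental transcription factors stood at 61.3% (35 of 56 covered over at least 50%; permutation, adjusted random-list p = 0.000467), with PAX7 at 1.07 and PAX5 at 1.03, whereas PAX6 (-0.29; 75.7% covered with any log2 ratio above 0) and GATA6 (-0.48) had no base in a domain. With a log2 ratio of 0.5 or more, the neuronal and the developmental list no longer stood apart (percentiles 71.5 and 87.5).

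HOX genes, which set position along the body axis, were divided. Of 39 members, 21 were covered over at least 50% and 15 had no base in a domain. HOXC4 and HOXC6 were wholly covered at 0.75 and 0.47 (HOXC6 not at all when a log2 ratio of 0.5 or more was required), and HOXA3 and HOXB3 had no coverage at -1.43 and -3.04. The list mean of 54.0% missed the threshold (permutation, adjusted random-list p = 0.0516), and its place depended on the setting, with adjusted p from 0.00084 to 0.997 over the alternatives. It passed in 5 alternatives, autosomes alone among them (54.0% against 36.4%), was level with random lists under a stricter p (30.4% for each, percentile 50.2), did not stand apart as 4 loci (percentile 81.1) or at an adjusted p of 0.01 (percentile 91.6), and fell below all random lists when a log2 ratio of 0.5 or more was required (4.66% coverage, percentile 0).

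Proliferation genes, which act in the cell cycle, did not stand apart as a list (24.3%, percentile 18.0), and 7 of 30 (23.3%) were covered over at least 50%, against 32.1% for random lists. MKI67, the proliferation marker, lay wholly in an enriched segment of 415 kb at 0.68 (0.64 to 0.72), and E2F2, a cell cycle transcription factor, was wholly covered at a mean of 1.04. BUB1 (0.00) and MCM6 (-0.89) had no base in a domain. In promoter windows of 1 kb on each side, the list fell below random lists (13.3% against 30.7%, percentile 1.19). NF-kB and C/EBP regulators, which drive SASP transcription, had a mean of 19.1% (percentile 8.04). Of its 20 members, 4 were covered over at least 50% and 2 lie on X, so autosomal genes were among the covered ones. The X-linked members IKBKG (0.98) and IRAK1 (0.44) were wholly covered, but IRAK1 had no coverage under a stricter p. On autosomes alone the list fell below random lists (10.1%, percentile 1.36). NFKB1 was at -3.26 and STAT3 at -3.09. Interferon and innate response genes did not stand apart (32.8%, percentile 35.5): MX1 (0.44; no coverage at a log2 ratio of 0.5 or more) and MX2 (0.97) were wholly covered, and RIGI, a sensor of viral RNA, had no coverage at -2.92.

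Clustered gene families went to both extremes. Keratin-associated proteins, components of hair, were covered at 94.7% (89 of 94 members) and olfactory receptors at 77.9% (311 of 399), both above all 10000 random lists (49.4% and 46.9% on average). Replication-dependent histone genes stood at 4.98%, with 63 of 67 members outside domains and a median log2 ratio of -2.03, against 59.3% for length-matched lists. H2AC1 was wholly covered at 0.17, and H2BC4 was at -2.24. Zinc finger genes named ZNF stood at 11.9%, with 390 of 476 outside domains. ZNF536 was wholly covered at 0.66, and ZNF521 was at -3.12. Clustered protocadherins did not stand apart (22.3%, percentile 10.2), with PCDHAC1 wholly covered at 0.34 and PCDHGA1 at -2.15, but lay below all random lists in promoter windows (5.66%) and above most by the median log2 ratio (percentile 99.8). All 53 members form 1 locus, so their percentiles describe 1 stretch of the genome. Counted as 5 loci each, the keratin-associated and the histone family did not pass (percentiles 96.6 and 8.32). At a log2 ratio of 0.5 or more, olfactory receptors fell below random lists (16.4%, percentile 0), keratin-associated proteins no longer stood apart (percentile 77.3), and H2AC1 and PCDHAC1 had no coverage.

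**Figure D5:**
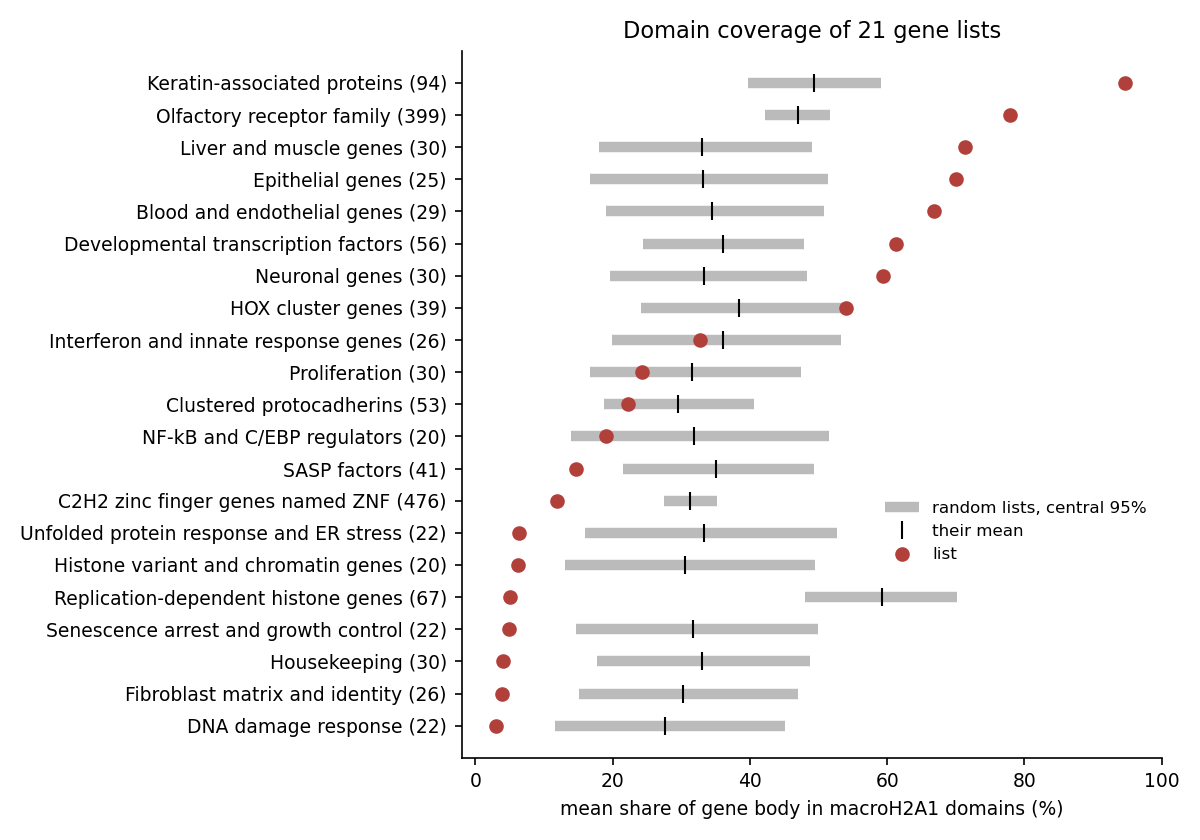
Mean percent of the gene body in macroH2A1 domains for 21 gene lists (red points, number of measured genes in brackets), with the mean (black tick) and central 95% (grey bar) of 10000 length-matched random lists. Lists run from DNA damage response genes at 3.08% to keratin-associated proteins at 94.7%.

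Among wholly covered genes, the 10 with the highest ratios began with SCGB1C1, a secretoglobin gene at the tip of chromosome 11. It lay in a domain of 4.12 kb at 1.76 (1.498 to 2.02, from 696 ChIP and 147 input reads). PVALEF on chromosome 17 followed at 1.47, then PAX4, a pancreatic transcription factor on chromosome 7, at 1.46, and RTP5 at 1.41. KRT9, KRT14, KRT16 and KRT17, keratins of stratified epithelia, shared 1 domain on chromosome 17 (39712529 to 39799809) at 1.38 (1.299 to 1.47). AL591806.1 (1.40) and NPIPB7 (1.38) completed the 10, and the NPIPB7 segment rested on 183 ChIP and 50 input reads. AL591806.1 and NPIPB7 had no coverage under a stricter p, and SCGB1C1 had none with domains of 5 kb or more.

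Of the 10 widest domains by coordinates, which count unsequenced bases, 7 spanned a centromere, 2 lay on the X chromosome and 1 on the long arm of chromosome 16. The 2 widest were those on chromosome 9 (4.23 Mb of known sequence, with SPATA31A7 and FAM27D1) and chromosome 16 (3.18 Mb, with TP53TG3D and TP53TG3E). The others over centromeres were on chromosomes 11 (FOLH1, TRIM49B; 5.41 Mb known, mean log2 0.64), 21 (TPTE, POTED; 2.60 Mb known), 7 (ZNF716, ZNF479; 2.36 Mb), 12 (CPNE8, ALG10B; 2.48 Mb) and 8 (POTEA; 2.05 Mb). Away from centromeres, the widest were 9.04 Mb at Xq21 (86891096 to 95934984) with PCDH11X, a protocadherin gene, at a mean log2 of only 0.19, 6.02 Mb at Xq27 with SLITRK4 and SLITRK2 (0.13), and 5.21 Mb on chromosome 16 with CDH8, a cadherin gene (0.15). By known sequence the Xq21 domain was the widest.

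Along chromosomes, domains avoided the darkest Giemsa bands and gathered into territories. In bands of the darkest stain, domains took up 33.3% of known sequence, 0.715 times the shifts. In unstained bands they took up 49.8% (1.05 times) and in bands of intermediate stain 55.5% (1.16 times), each at a permutation p = 0.002, the smallest possible. The remaining 2 stain classes did not pass the test (permutation p = 0.671 and 0.611). At a log2 ratio of 0.5 or more, the intermediate class no longer passed (1.08 times, permutation p = 0.248), and the class one step lighter and the class one step darker did (1.35 and 0.513 times). The median gap between neighbouring domains was 70.9 kb against 115 kb for random placements. Of 2847 bins of 1 Mb, 1311 had at least 50% of their sequence in domains against 1204 on average, and 242 had no domain against 20.6 (permutation p = 0.002 for each, the smallest possible).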

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

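The test on the input library was chosen after the result was seen. Matching on gene density was among the settings fixed before the data were examined. The other tests in this part were chosen after the patterns but before their own results were seen. No biological explanation was tested, because the labels give a single condition.

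Outside the chromosomes used, the first 17 bases of the mitochondrial chromosome had a log2 ratio of 0.73 (14407 ChIP and 6200 input reads). This segment is far shorter than the sonicated pieces of about 500 bp and lies at the edge of the reference sequence. It therefore cannot place macroH2A1 on mitochondrial DNA. The 3 remaining mitochondrial segments stood at -1.87, -1.56 and -0.63.

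Depleted segments had ratios far below those of enriched segments. An excess of input reads in depleted segments is one technical explanation that could lower them. Input reads per kb of depleted segments listed at 0 were 1.00 times those of enriched segments (14.9 against 14.8), which argues against it, whereas ChIP reads per kb were 8.97 against 29.9. Reads of these segments could not be recovered one by one. The depleted value is therefore the remainder of the implied totals, whose fit was not tested on simulated data. It includes the mitochondrial segments listed at 0. It also assumes that enriched segments at the top of the p column had the input density of the other enriched segments. Depleted segments with recovered numbers, which need neither a remainder nor that assumption, had 14.0 input and 16.8 ChIP reads per kb. They were 18.5% of depleted segments on the chromosomes used, with a −log10 p of at most 6.25. Being the weaker ones, they cannot show the input density of segments listed at 0.

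SASP genes were less covered than lists matched on length. Neither GC content nor gene-dense surroundings is likely to be the whole cause, since the list stood at percentile 0.01 among lists matched on length and GC, and at 0.02 among those matched on length and gene density. Whether the low coverage is centred on the genes stays open. The difference between flanks of 100 kb and gene bodies was 22.97 percentage points against 11.3 for random lists (percentile 97.9; permutation, adjusted random-list p = 0.0663), but it contains the low body coverage itself, and the flanks stood at 37.6% against 46.4% (percentile 3.24). How the genes' transcription relates to this also stays open, since no expression data were analysed here.

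The domain share was lower downstream of TSSs than upstream. Among the 8785 TSSs with as much or more GC upstream, the share was still 18.1 percentage points higher upstream (47.2% against 29.1%; bootstrap interval 17.0 to 19.2). This argues against a GC difference only if GC lowers the share. If GC raised it, these TSSs would show an upstream excess, so they cannot test that case. Over all TSSs the difference was 15.1 points, and TSSs with more GC downstream were not taken alone. Whether GC contributes thus stays open. The bootstrap drew single TSSs, and neighbouring TSSs can share a domain, so the interval may be too narrow. The interval does not cover the spread between cultures. Whether the asymmetry comes from depleted segments that begin at gene starts stays open. Although 4914 TSSs lay within 2 kb of a border to a lower ratio in the direction of transcription, against 605 on average in the shifts (493 to 684), the profile already fixes a count above the shifts. The share fell from 42.1% at 2 kb upstream to 32.7% at 2 kb downstream, which alone asks for such borders at about 1881 TSSs, and borders to a higher ratio were also in excess, at 1225 TSSs (2.02 times the shifts).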

How the results depend on the processing

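Tests with any log2 ratio above 0, a log2 ratio of 0.5 or more, an adjusted p, GC matching, the median log2 ratio or other TSSs together with other domains, and all alternatives for the TSS profile and named genes, were chosen after the data were seen. Of 432 values under alternatives, 391 were kept (236 of 254 planned). A tested value was kept if it stayed on its side of the threshold, and a change of direction counted only where either value passed. Domain counts were kept within 1.5-fold, and the rank of X if unchanged. Shares of known sequence and correlations with width were never counted as kept. TSS depletion kept in 24 of 26 (all 26 from 0.636 to 1.09 times the shifts), gene features in 32 of 32, clustering in 26 of 26, bands in 37 of 40 and SASP coverage in 13 of 15 (adjusted random-list p, by permutation, from 0.000764 to 0.266). Of 130 named genes, 101 stayed on the same side of 50% coverage in all 7 other domain sets, and of 41 SASP genes, 37. CSF2 was covered with domains under 10 kb apart joined, CXCL6 (81.0%) and MMP12 with any log2 ratio above 0; SCGB1C1 was lost at 5 kb or more and NPIPB7 under a stricter p. No paired analysis was possible because the groups share only 1 replicate number and no result is a test between libraries. Depth limits narrow segments most, and depleted segments listed at 0 have no interval. Except where stated, the cause was not tested.

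The number of domains was 4586 under a stricter p and 19449 with inner blocks. The share of known sequence was 33.9% and 46.4% in these settings, 47.28% for domains of 5 kb or more, 47.5% joined, 52.3% with any log2 ratio above 0, 22.1% at 0.5 or more, 46.3% at an adjusted p and 47.1% over whole chromosome length. A log2 ratio of 0.5 or more removes weak segments by construction, and wide enriched segments had lower ratios. Whether this accounts for the changes in that setting was not tested. There, TSSs of all annotated genes reversed to 1.09 times the shifts (permutation p = 0.002), and TSSs with a domain within 1 kb came to 0.949 (permutation p = 0.118). X ranked 15, and the 3 middle band classes, light to dark, stood at 1.35, 1.08 and 0.513 times the shifts. HOX genes and olfactory receptors reversed to percentile 0, SASP genes were at 1.98 (permutation, adjusted p = 0.0571) and protocadherins at 0. Developmental, neuronal and keratin-associated genes fell to 87.5, 71.5 and 77.3. By the median log2 ratio, percentiles were 12.3 for SASP, 3.26 for DNA damage, 1.96 for fibroblast genes and, reversed, 99.8 for protocadherins. Proliferation genes came to 1.19, HOX to 98.3 and protocadherins to 0 in promoter windows. HOX genes came to 99.5 with inner blocks, 98.0 at 5 kb or more, 99.02 on autosomes and 99.3 with any log2 ratio above 0. NF-kB regulators came to 1.36 on autosomes and protocadherins to 1.99 with GC matching. With neighbours as 1 locus, keratin-associated proteins were at 96.6 and replication histones at 8.32. The rank correlation of ratio with width was -0.12 with any log2 ratio above 0. The p column (0.55) and the block count (0.49) grow with width by construction, so their positive correlations do not bear on it.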

Other observations

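The comparisons in this part were chosen after the main results were seen. Domains were frequent near both ends and centres of chromosomes. Within 5 Mb of a chromosome end, 59.0% of known sequence lay in domains, 1.21 times the circular shifts (permutation of positions, placement p = 0.002, the smallest that 1000 shifts allow), and the median log2 ratio of enriched segments there was 0.85. In 19 of 23 chromosomes this share exceeded the chromosome's own. Within 5 Mb of a centromere band it was 57.2%, 1.18 times the shifts (permutation p = 0.00999), and 18 of 23 chromosomes were above their own share.

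Gene types differed in how often their starts lay in domains. Processed pseudogenes, which are copies of messenger RNAs inserted back into the genome, had 54.7% of 9949 TSSs in domains, 1.14 times the shifts (permutation p = 0.002, the smallest possible). Long noncoding RNA genes had 44.4% of 18591 TSSs in domains (0.931 times, with the same smallest p), snRNA genes 44.1% (0.930 times, permutation p = 0.00999) and microRNA genes 45.3% (0.932 times, p = 0.022). Reads from near-identical copies cannot be placed with certainty, and how they were handled is not given in the sources used here.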
